A study of Homo sapiens with 6 samples.

How the data were processed

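RNA-seq was done on 6 libraries of WTC11-derived astrocytes in alginate capsules, 3 given vehicle and 3 given ITC for 48 hours. Per the labels' protocols, RNA was extracted with a column kit including a DNase step, and poly-A selected libraries were prepared with NEB chemistry and sequenced by a service company. Groups and replicate numbers were taken from the sample titles. The series description names separate batches of capsules, each divided between the treatments, and does not say that the replicate number marks the batch.

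The authors deposited a table of 30949 genes with Ensembl identifiers. Its whole-number counts per gene are raw, per the file headers and the values. The aligner, the counting program and its use of strand are not given in the sources used here. The submitters' processing notes name GRCh38 (hg38) and DESeq2, without a version. The deposited normalized signal is the counts divided by a size factor that is constant within each library, tested on the values. The deposited log2 fold changes, per the file headers, are of vehicle over ITC, so that negative values are higher in ITC. The deposited p-values and adjusted p-values come with them, and 9001 genes carry an adjusted p of exactly 1. The deposited FPKM values, per the file headers, use the listed gene length and a scaled library size that was 84.3% to 108% of the total count. The authors' table lists genes with a total count of at least 2 over the 6 libraries. Of the gene identifiers, 99.9% had identical coordinates in GENCODE 29, and 26 genes had names turned into calendar dates, which were replaced by the symbol of the same identifier where one was found. There were 0 columns of samples outside the mapped ones, and 0 rows that name no gene.

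Counts were tested with edgeR 4.0.16 in R 4.3.3, keeping genes by filterByExpr, scaling by TMM and using the quasi-likelihood test without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. TMM factors were 1.069, 1.099 and 1.082 for vehicle and 0.886, 0.933 and 0.953 for ITC. The SE of a log2 fold change is its size divided by the square root of F. It can be too small where 1 group has few counts. Gene lists, 25 of responses and 10 of cell type markers, were fixed before the data were examined, and 617 of their 644 distinct genes had a row. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with an estimated correlation and fry beside it. Camera compares the members with the other genes, whereas fry asks whether the members changed at all. Principal components used the 500 most variable genes. A fold against a group with no count was computed against a floor of 3 counts over the group, and a ratio against 1 to 3 counts has a 95% exact binomial interval; both cover counting error only. Depth of 17398921 to 29941685 counts per library sets these floors. DESeq2 1.42.0 was run as an alternative. Without a block it gave the log2 fold changes of the authors' table within 2.49e-08, and 0 genes were called in exactly 1 of them. Exact permutation tests and figures used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.

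Named genes were chosen by a rule written before the data were examined. It takes the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 1 CPM and groups that do not overlap. From each response list it takes up to 4 called members with the smallest p and up to 2 uncalled members with the highest CPM, and from each marker list up to 3 with the highest CPM and up to 3 called with the smallest p. It always takes GFAP, C3, IL1R1, TNFRSF1A, TNFRSF1B, IL1A, TNF, IL6, CXCL10, S100B, AQP4 and SLC1A3. Other genes are named in the text as chosen after their values were seen. Some genes that the rule takes are not reported here. Exon overlaps were computed with GENCODE 29, and 8 named genes share over 25% of their exon bases with other genes.

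The pipeline was tested on simulated counts of 16756 genes with the mean levels, dispersions and library sizes of this comparison. It called 69% of 100 genes changed 2-fold and 88% of 100 genes changed 4-fold in the right direction, and 11 unchanged genes. For simulated lists of 20 genes, the camera p-value was 1.3e-24 with all members raised and 0.222 with none changed. Simulated genes were drawn independently, so the list test was not tried on correlated members. Only 200 genes were changed, equally up and down, so scaling was not tried under changes as wide as in these data. The alternatives were other scalings, other filters on low counts, a replicate block, leaving out each library, DESeq2, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), stricter thresholds, protein-coding genes only and other list tests. Scaling by library size only was added after seeing the data.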

Results

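Polyadenylated RNA was sequenced from 6 cultures of human astrocytes grown as floating aggregates inside alginate capsules. The astrocytes derive from WTC11, an established human induced pluripotent stem cell line. For 48 hours, 3 cultures received vehicle and 3 received ITC, a mixture of interleukin 1 alpha, tumor necrosis factor alpha and complement C1q. Per the series description, the capsules came from separate batches that were each divided between the treatments. Total counts per library were 20203844, 17398921 and 29941685 for vehicle replicates 1, 2 and 3, and 18623454, 19327421 and 17808993 for ITC replicates 1, 2 and 3. Mitochondrial transcripts took 4.19% ± 0.737 of the counts in vehicle (SD, n = 3) and 3.06% ± 0.398 in ITC (SD, n = 3), with every vehicle library above every ITC library (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The number of genes with a count ranged from 24136 to 26577 in vehicle and from 21812 to 23884 in ITC. Genome positions below are on GRCh38 as the authors' table gives them. CPM values are counts scaled to a common library size with TMM factors and are given as mean ± SD over n = 3 libraries per group. Fold changes are log2 of ITC over vehicle ± SE.

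The libraries separated by treatment. The first principal component of the 500 most variable genes held 96.7% of their variance and the second held 1.3%. Spearman correlations across genes ranged from 0.979 to 0.992 within groups and from 0.894 to 0.921 between groups. Libraries within a group differed by more than counting noise (lowest chi-square per degree of freedom of a pair 10.4), which does not show that they are independent. Each was counted as a replicate because the series description names separate batches.

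The comparison asks which transcripts differ in the encapsulated astrocytes after 48 hours of ITC. The largest rises included the chemokines CXCL1 and CXCL8, the granulocyte growth factor CSF3, the acute-phase gene SAA2 and the endosomal RNA sensor TLR7. CXCL8, a neutrophil chemoattractant (chromosome 4, 73740506 to 73743716), went from 0.494 ± 0.111 to 1960 ± 359 CPM, a log2 change of 11.91 ± 0.30. CXCL1 on the same chromosome (73869393 to 73871242) rose by 13.74 ± 0.37, from 4 counts over the vehicle group to 834 ± 152 CPM. With so few vehicle counts its fold is less certain than the SE shows. TLR7 (chromosome X, 12867083 to 12890380) had no count in the 3 vehicle libraries and 95.2 ± 8.75 CPM in ITC, at least 2310-fold higher against a floor of 3 counts over the group. On the same floor CSF3 was at least 698-fold higher, SAA2 at least 417-fold, TDO2 at least 414-fold and TNIP3 at least 384-fold. SAA2 has a close paralog in SAA1, so the division of reads between them is uncertain. OR2I1P, annotated as an olfactory receptor gene (chromosome 6, 29550407 to 29557721), was at least 6930-fold higher, at 286 ± 29.2 CPM in ITC, and is uncertain because 836 bases of its exons overlap exons of UBD, and 722 overlap exons of GABBR1, both on the opposite strand.

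The largest falls included MKI67, TOP2A and other genes of cell division, and single genes of other kinds. MKI67, the proliferation marker (chromosome 10, 128096659 to 128126385), fell by 6.37 ± 0.31 on the log2 scale, from 88.6 ± 27.7 to 1.06 ± 0.433 CPM. PBK, a mitotic kinase, fell by 6.31 ± 0.27 and SPC25, a kinetochore component, fell by 6.21 ± 0.41, to 7 counts over the ITC group. The peptide transporter SLC15A2 fell by 5.84 ± 0.24, the potassium channel KCNK2 fell by 5.95 ± 0.33 and CLEC19A fell by 6.11 ± 0.33. PRELP, a matrix proteoglycan, kept a ratio of ITC over vehicle of 0.00283 (95% counting interval 7.14e-05 to 0.0158), and the GABA receptor subunit GABRG1 kept 0.0148 (0.00178 to 0.0541).

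edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 6599 of 16756 tested genes (39.4%) at an adjusted p under 0.05, 3423 higher and 3176 lower in ITC. Of the called genes, 1680 rose and 1908 fell by at least 2-fold, and 234 rose and 148 fell by at least 16-fold. The groups did not overlap in 50.1% of tested genes, against 10% by chance for 3 against 3. The balance of directions depends on the scaling. With upper quartile scaling 2662 genes were higher and 4059 lower, and with library size alone, an alternative chosen after seeing the data, 2282 were higher and 4804 lower, as the median log2 change of all genes moved from -0.01 to -0.16 and -0.24.

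**Figure D1:**
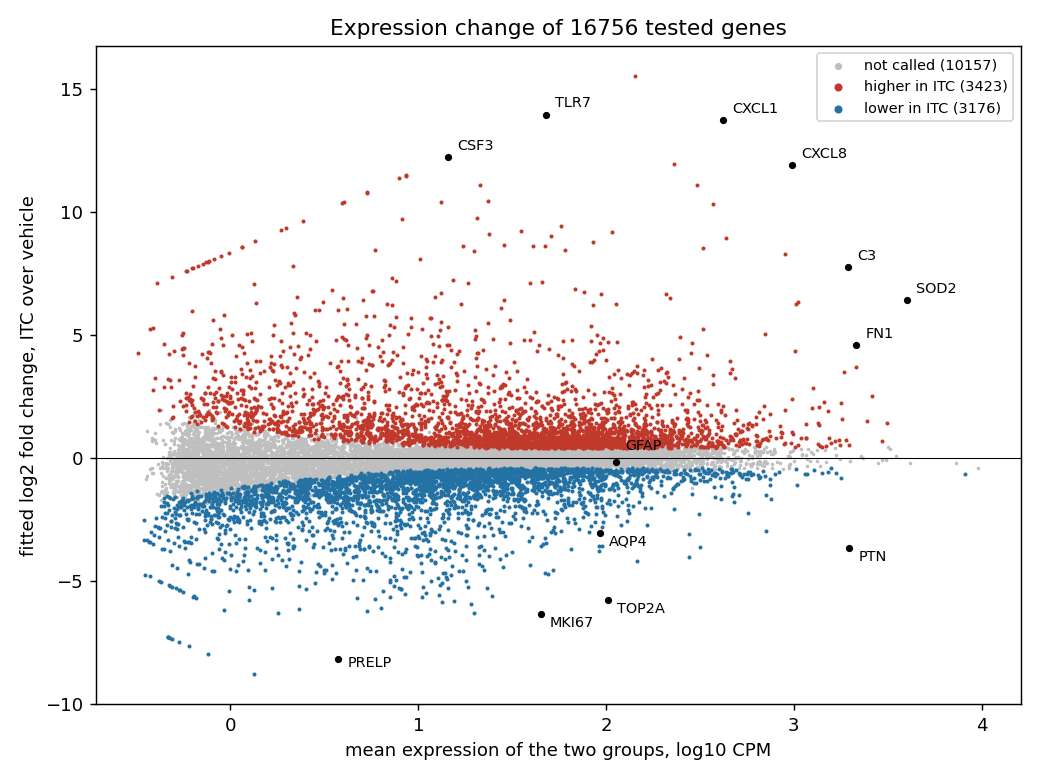
Fitted log2 fold change (ITC over vehicle) against the log10 of the mean CPM of the groups for the 16756 tested genes, with 3423 genes called higher in red, 3176 called lower in blue and the rest in grey. CXCL8 and C3 lie high at the right, MKI67 and TOP2A lie low, and GFAP lies near 0; fitted values of genes with no vehicle count, such as TLR7 and CSF3, depend on the prior count.

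Chemokine transcripts rose nearly throughout. Of 17 tested chemokines, 15 rose, 1 fell and 1 was not called (16 and 1 adjusted over the list alone), with a median log2 change of 8.40. CXCL6 rose by 11.94 ± 0.31, from 8 counts over the vehicle group to 457 ± 50.7 CPM. CXCL2 rose by 11.10 ± 0.35, to 606 ± 60.4 CPM. Reads of CXCL1 and CXCL2 can be shared between these similar genes. CXCL10, a T cell chemoattractant, rose by 8.40 ± 0.33, from 0.123 ± 0.102 CPM (8 counts over the vehicle group) to 39.5 ± 3.49 CPM. The member that fell was CXCL12, a homeostatic chemokine chosen here after its values were seen, by 1.44 ± 0.27. Of 16 cytokines and hematopoietic factors, 13 rose and 3 were not called (13 and 0 adjusted over the list alone), with a median of 3.47. IL32 rose by 7.09 ± 0.35, LIF by 3.73 ± 0.17 to 125 ± 15.6 CPM and CSF1 by 2.64 ± 0.18 to 325 ± 47.2 CPM. IL6 rose by 6.82 ± 0.49 but reached only 6.91 ± 1.99 CPM, and IL1A rose by 5.49 ± 0.68 to 4.08 ± 1.98 CPM. TNF was not analysed here. IL33 (-0.89 ± 0.41) and IL18 (0.11 ± 0.46) were not called. Both lists were called by camera and stayed called with an estimated correlation (adjusted p = 0.0253 for each).

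All 22 tested members of the NF-kappa-B pathway and its feedback regulators rose, with the same count adjusted over the list alone and a median of 4.05. SOD2, the mitochondrial superoxide dismutase (chromosome 6, 159669057 to 159745186), rose by 6.42 ± 0.19, from 92.5 ± 6.62 to 7920 ± 338 CPM. TNFAIP2 rose by 8.92 ± 0.28, the apoptosis inhibitor BIRC3 by 8.52 ± 0.30 and TNFAIP3, a negative regulator of the pathway, by 6.66 ± 0.23. Of 21 genes of the p53 and apoptosis list, 16 rose and 5 were not called (16 and 0 adjusted over the list alone), among them BID (2.79 ± 0.17) and the death receptor TNFRSF10B (2.12 ± 0.16). The list holds both promoters and inhibitors of cell death, BIRC3 among the latter. Both lists stayed called with an estimated correlation (adjusted p = 0.0253 for each). Receptors and adaptors of interleukin 1 and TNF included 11 that rose and 2 that were not called of 13 tested (11 and 0 adjusted over the list alone). The interleukin 1 receptor IL1R1 rose by 3.28 ± 0.18, from 3.73 ± 0.177 to 36.3 ± 3.98 CPM, TNFRSF1B by 2.96 ± 0.41 and TNFRSF1A, the more abundant TNF receptor, by 1.04 ± 0.19 to 300 ± 58.1 CPM. The adaptors IRAK4 (0.09 ± 0.17) and TRAF6 (-0.04 ± 0.17) were not called, and this list lost its call with an estimated correlation (adjusted p = 0.0934).

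Antigen presentation genes of class I rose in all 18 tested members, also adjusted over the list alone, with a median of 2.81 (adjusted p = 0.0827 with an estimated correlation). HLA-B rose by 4.16 ± 0.22, from 36.4 ± 2.62 to 652 ± 189 CPM, the peptide transporter TAP1 by 3.82 ± 0.22, and the immunoproteasome subunits PSMB8 and PSMB9 by 4.37 ± 0.25 and 5.05 ± 0.30. HLA genes are near-identical in parts, so the division of reads among them is uncertain. Of 36 interferon-stimulated genes, 30 rose, 2 fell and 4 were not called (30 and 2 adjusted over the list alone), with a median of 2.22 (adjusted p = 0.0884 with an estimated correlation). GBP1 rose by 9.23 ± 0.35, GBP2 by 6.76 ± 0.21, the RNA sensor IFIH1 by 3.54 ± 0.22 and HERC6 by 3.21 ± 0.22. The members that fell, chosen after their values were seen, were IFIT1 by 1.06 ± 0.21 and IFITM1 by 0.88 ± 0.18; IFITM1 shares 32.5% of its exon bases with IFITM2. IFITM3 (0.19 ± 0.19) and IFIT2 (0.10 ± 0.17) were not called. Class II presentation was not called as a list (camera adjusted p = 0.404); 3 of 6 tested members rose, also adjusted over the list alone, to between 1.60 ± 0.221 CPM for CD74 and 5.35 ± 0.224 CPM for HLA-DPA1. HLA-DPB1 (1.16 ± 0.36) lost its call without vehicle replicate 1 (adjusted p = 0.052 by edgeR) or without ITC replicate 1 (adjusted p = 0.125), and with library size only.

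Markers of reactive astrocytes moved in several directions. GFAP, the intermediate filament most used as a marker of reactivity (chromosome 17, 44903161 to 44916937), was at 121 ± 25.9 CPM in vehicle and 106 ± 19.6 CPM in ITC, a log2 change of -0.19 ± 0.19 (edgeR adjusted p = 0.454). Of 12 tested pan-reactive genes, 8 rose, 1 fell and 3 were not called; CP, the ferroxidase ceruloplasmin, rose by 5.24 ± 0.24, OSMR by 2.17 ± 0.17, and LCN2 was at least 96.0-fold higher on the floor of 3 counts over the vehicle group. The sphingosine receptor S1PR3, chosen after its values were seen, fell by 1.45 ± 0.24. Of 9 genes of the A1 list, defined in the literature for neuroinflammatory astrocytes, 6 rose, 1 fell and 2 were not called. C3, the central complement component (chromosome 19, 6677704 to 6730562), rose by 7.76 ± 0.23, from 17.8 ± 2.13 to 3840 ± 659 CPM, and FBLN5 by 2.89 ± 0.19. AMIGO2, chosen after its values were seen, fell by 0.92 ± 0.20, and SERPING1 (-0.33 ± 0.20) and FKBP5 (-0.36 ± 0.20) were not called. Of 10 genes of the A2 list, 8 rose and 2 were not called; PTGS2, the inducible cyclooxygenase, rose from 0.188 ± 0.0429 to 101 ± 16.3 CPM, PTX3 by 5.04 ± 0.19 and SPHK1 by 1.79 ± 0.17. Counts adjusted over the list alone were the same for all 3 lists, and their medians were 1.09, 2.89 and 0.69. All 3 were called by camera and lost the call with an estimated correlation (adjusted p = 0.0949, 0.194 and 0.0934).

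Complement genes were split. Of 15 tested, 5 rose, 2 fell and 8 were not called, also adjusted over the list alone. Beside C3, the proteases C1S and C1R rose by 6.50 ± 0.21 and 3.89 ± 0.18, and CFB, which shares 45% of its exon bases with another protein-coding gene, by 4.55 ± 0.43. Chosen after their values were seen, CD59 rose by 0.74 ± 0.15 while C5 fell by 1.82 ± 0.26 and C4A by 0.82 ± 0.30. C4A has a near-identical copy and lost its call in 5 of 6 leave-one-out fits (edgeR adjusted p 0.0513 to 0.138), with limma-voom (0.135) and in both fits of FPKM (0.128 and 0.149). Clusterin, CLU, was high in both groups and not called (0.09 ± 0.20). The camera call of the list (adjusted p = 0.0283) was lost with an estimated correlation (adjusted p = 0.144) and with a filter of at least 1 CPM in 3 libraries (0.0525). It was also lost without vehicle replicate 3 (0.0675), without ITC replicate 1 (0.0846) and with the replicate block (0.0936).

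**Figure D2:**
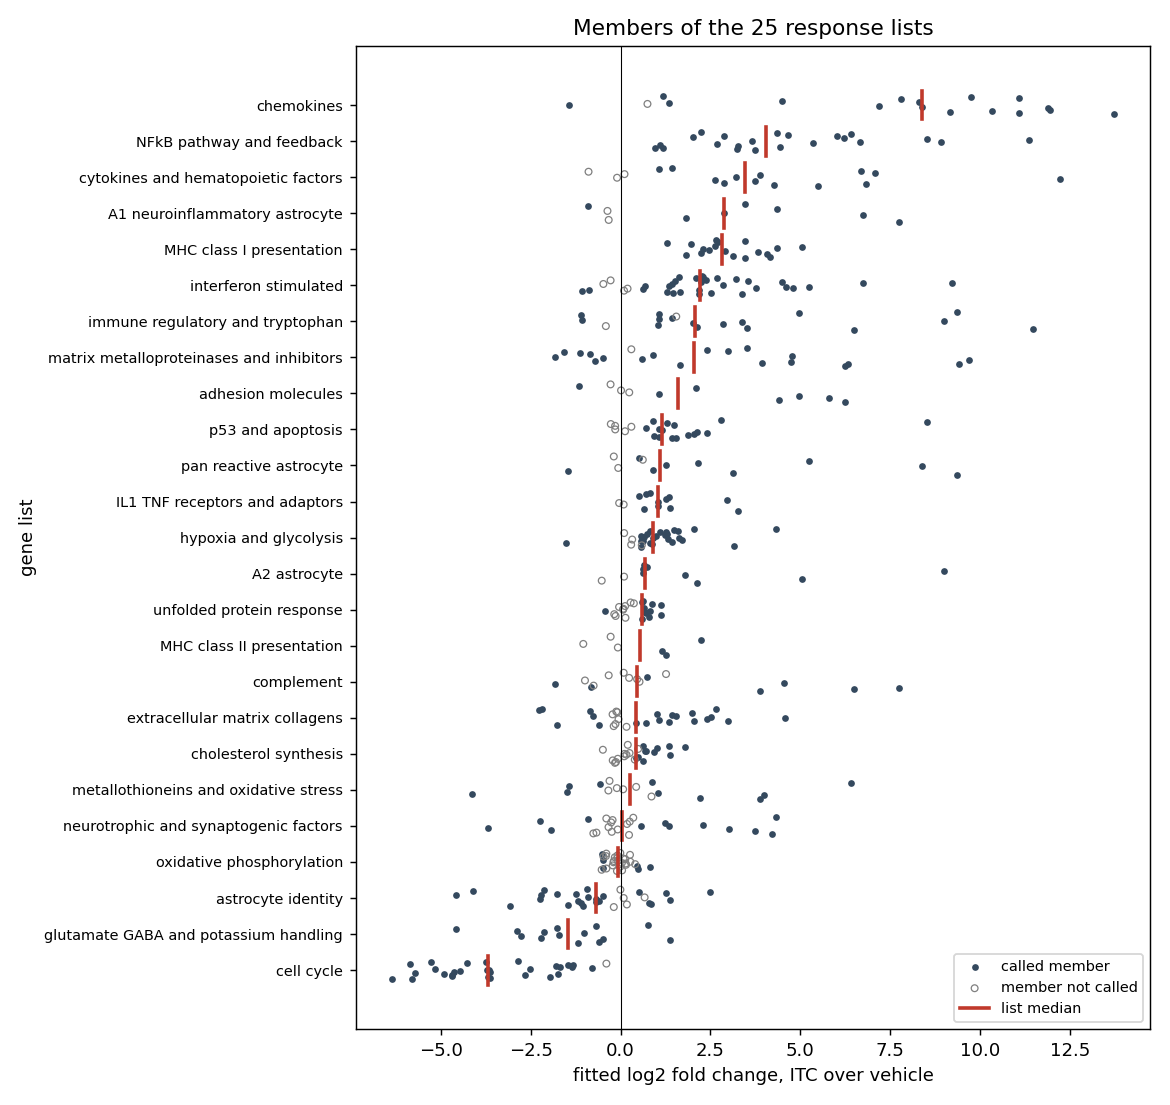
Fitted log2 fold change (ITC over vehicle) of each tested member of the 25 response lists, with called members filled, uncalled members open and the list median as a red bar. Chemokines have a median of 8.40, members of the NF-kappa-B list all lie above 0, and the cell cycle list has a median of -3.67; values of genes with no vehicle count depend on the prior count.

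Adhesion and matrix genes changed widely. Of 10 adhesion molecules, 6 rose, 1 fell and 3 were not called, with a median of 1.59 (adjusted p = 0.0934 with an estimated correlation of -0.08). ICAM1, a leukocyte ligand, rose by 6.26 ± 0.22, from 26.4 ± 2.55 to 2020 ± 372 CPM, VCAM1 by 4.40 ± 0.20 and ICAM5 by 4.95 ± 0.30. NCAM1, chosen after its values were seen, fell by 1.16 ± 0.18. Of 20 metalloproteinases and inhibitors, 13 rose, 6 fell and 1 was not called, with a median of 2.03 (adjusted p = 0.128 with an estimated correlation). MMP3, or stromelysin, rose by 9.42 ± 0.41, the collagenase MMP1 by 6.24 ± 0.28 and ADAMTS9 by 3.52 ± 0.17, and MMP12 had a ratio of 1200 (95% counting interval 214 to 47300). Among genes chosen after their values were seen, MMP7 rose by 6.33 ± 0.50, to 2090 ± 497 CPM, and the inhibitor TIMP3 fell by 1.14 ± 0.20. Of 27 matrix genes and collagens, 14 rose, 6 fell and 7 were not called, with a median of 0.44 (adjusted p = 0.241 with an estimated correlation). Fibronectin, FN1, rose by 4.59 ± 0.22, from 171 ± 12.3 to 4110 ± 1140 CPM, COL6A3 from 2.74 ± 0.12 to 21.8 ± 2.51 CPM, COL12A1 by 2.40 ± 0.16 and the crosslinking enzyme LOXL2 by 1.98 ± 0.16. Brevican, BCAN, a brain proteoglycan chosen after its values were seen, fell by 2.28 ± 0.25. SPARC (-0.22 ± 0.15) and COL11A1 (-0.06 ± 0.16) stayed abundant and were not called. Counts adjusted over the list alone were the same for all 3 lists.

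Astrocyte identity genes fell more often than they rose. Of 29 tested, 18 fell, 6 rose and 5 were not called, with a median of -0.69. AQP4, the astrocyte water channel (chromosome 18, 26852038 to 26865818), fell by 3.07 ± 0.18, from 166 ± 19.4 to 19.7 ± 2.94 CPM. MLC1 fell by 4.12 ± 0.24 and angiotensinogen, AGT, by 2.21 ± 0.17. S100B fell by 1.04 ± 0.16 and the glutamate transporter SLC1A3 by 0.59 ± 0.16. The members that rose included, chosen after their values were seen, ID3 (2.48 ± 0.20), CD44 (1.28 ± 0.17), SOX9 (0.85 ± 0.21) and NFIA (0.80 ± 0.20). Of 14 genes for glutamate, GABA and potassium handling, 12 fell and 2 rose, with a median of -1.45. The potassium channel KCNJ10 fell by 2.14 ± 0.23 and ATP1B2 by 1.78 ± 0.20, while glutamine synthetase, GLUL, rose by 1.38 ± 0.16, from 349 ± 33.9 to 911 ± 91.9 CPM. The other member that rose, SLC38A3, chosen after its values were seen, lost its call in some leave-one-out fits (edgeR adjusted p 0.0565 to 0.122). Counts adjusted over the list alone were the same for both lists. Markers of neurons and of neural progenitors fell in the same libraries, with list medians of -1.07 and -1.31 (adjusted p = 0.141 and 0.173 with an estimated correlation). Both astrocyte lists were called by camera and lost the call with an estimated correlation (adjusted p = 0.314 and 0.158).

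**Figure D3:**
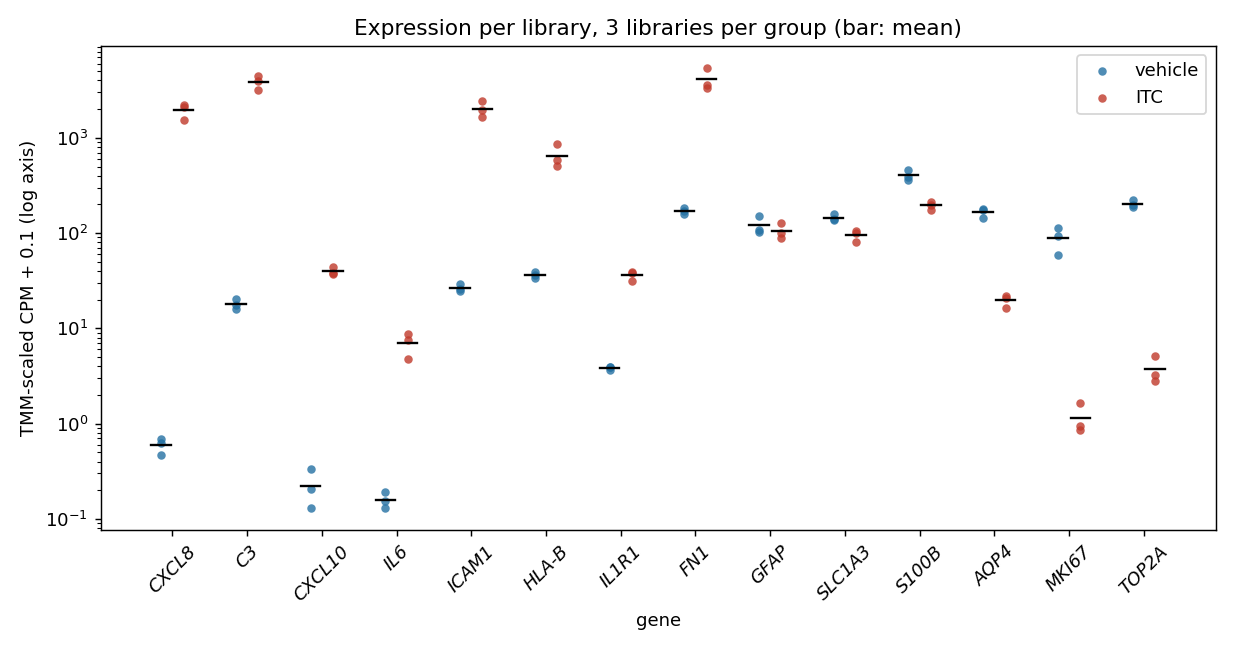
CPM plus 0.1 of 14 genes in each library on a log axis, with vehicle in blue, ITC in red and bars at the mean of 3 libraries. The genes plotted were picked after their values were seen; C3 went from 17.8 to 3840 CPM, AQP4 from 166 to 19.7 CPM, and the groups overlap for GFAP.

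Cell cycle genes fell together. Of 30 tested, 29 fell and 1 was not called (30 fell adjusted over the list alone), with a median of -3.67. TOP2A, a topoisomerase of dividing cells (chromosome 17, 40388516 to 40417950), fell by 5.79 ± 0.24, from 201 ± 17.5 to 3.62 ± 1.28 CPM. The survivin gene BIRC5 fell by 5.28 ± 0.25, the centromere protein CENPF by 3.71 ± 0.20 and the ribonucleotide reductase subunit RRM2 fell by 5.86 ± 0.44. TYMS, which shares 39.1% of its exon bases with ENOSF1, was the member not called (-0.39 ± 0.16). The list stayed called with an estimated correlation (adjusted p = 0.0253). Of 10 neural progenitor markers, 8 were lower in the same libraries, with a list median of -1.31 (adjusted p = 0.173 with an estimated correlation). SOX2 and NES among them lost their calls in most leave-one-out fits.

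Genes of hypoxia and glycolysis rose more often than they fell. Of 29 tested, 24 rose, 1 fell and 4 were not called (25 and 1 adjusted over the list alone), with a median of 0.91 (adjusted p = 0.144 with an estimated correlation). The lactate exporter SLC16A3 rose by 4.34 ± 0.32, LDHA by 2.04 ± 0.20, PDK1 by 1.72 ± 0.18 and hexokinase HK2 by 1.64 ± 0.16, and GAPDH was not called (0.10 ± 0.19). EGLN3, chosen after its values were seen, fell by 1.52 ± 0.25. Of 23 genes of cholesterol synthesis and uptake, 11 rose and 12 were not called (13 rose and 1 fell adjusted over the list alone), with a median of 0.43 (adjusted p = 0.301 with an estimated correlation). LSS rose by 1.36 ± 0.20, and HMGCS1 was not called (-0.15 ± 0.21). Of 21 genes of the unfolded protein response, 11 rose, 1 fell and 9 were not called, with the same counts adjusted over the list alone and a median of 0.59 (adjusted p = 0.194 with an estimated correlation). XBP1 rose by 1.12 ± 0.17, while ATF4 (-0.14 ± 0.15) and the chaperone HSP90B1 (0.08 ± 0.17) were not called. The member that fell, PDIA4, chosen after its values were seen, lost its call in several leave-one-out fits (edgeR adjusted p 0.101 to 0.201). Oxidative phosphorylation was not called as a list (camera adjusted p = 0.809), with 3 genes up, 3 down and 24 not called of 30, and 0 called adjusted over the list alone. ATP5F1A was at -0.09 ± 0.15, and the mitochondrial share of counts was lower in the ITC libraries. The list of metallothioneins and oxidative stress genes was not called (camera adjusted p = 0.298) but was by directional fry (adjusted p = 0.000153) and by camera without a filter on low counts (0.0287), with 6 up, 4 down and 6 not called of 16, the same adjusted over the list alone. MT2A rose from 11.8 ± 1.7 to 189 ± 74.3 CPM and NQO1 fell from 107 ± 15.5 to 37.7 ± 1.7 CPM.

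Secreted growth factors and immune regulators differed in pattern. Of 24 neurotrophic and synaptogenic factors, 8 rose, 4 fell and 12 were not called, the same adjusted over the list alone, and the list was not called by camera (adjusted p = 0.404) but was by directional fry (0.000575). Pleiotrophin, PTN (chromosome 7, 137227341 to 137343865), fell by 3.68 ± 0.20, from 3640 ± 563 to 284 ± 43.4 CPM. The activin subunit INHBA rose by 4.31 ± 0.30 and GDNF by 4.20 ± 0.25, to 30.6 ± 3.25 CPM, while MDK was not called (-0.34 ± 0.17). Of 18 immune-regulatory and tryptophan pathway genes, 14 rose, 2 fell and 2 were not called, the same adjusted over the list alone, with a median of 2.06 (adjusted p = 0.0253 with an estimated correlation). Beside TDO2 and PTGS2, the nitric oxide synthase NOS2 rose by 4.97 ± 0.32 and the prostaglandin E synthase PTGES by 3.37 ± 0.19. The members that fell, chosen after their values were seen, were CD200 by 1.10 ± 0.16 and PTGS1 by 1.08 ± 0.38; PTGS1 lost its call in each of 4 leave-one-out fits by edgeR (without vehicle replicate 2, 0.0627; vehicle replicate 3, 0.125; ITC replicate 1, 0.0943; ITC replicate 2, 0.149) and with DESeq2 (0.0594).

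Markers of neurons, neural progenitors and ependymal cells fell more often than they rose. Of 15 neuron markers, 8 fell and 7 were not called, with a median of -1.07; MAP2 fell by 1.56 ± 0.17, from 700 ± 88.3 to 238 ± 36.8 CPM, NEFL by 2.04 ± 0.19 and DCX by 2.21 ± 0.26. Of 10 neural progenitor markers, 8 fell, 1 rose and 1 was not called, with FABP7 falling by 2.58 ± 0.27. PROM1, chosen after its values were seen, rose by 1.00 ± 0.19. Among those that fell, SOX2 lost its call in most leave-one-out fits (edgeR adjusted p 0.0504 to 0.0856). NES also did (0.0551 to 0.105), and in both limma fits of FPKM (0.057 and 0.0568). Of 9 choroid plexus and ependymal markers, 7 fell, 1 rose and 1 was not called, with a median of -1.19; the ciliogenesis factor FOXJ1 fell by 2.92 ± 0.20, from 92.4 ± 21.2 to 12.2 ± 1.78 CPM, and CLIC6 rose by 5.20 ± 0.24. These 3 lists were called lower by camera and lost the call with an estimated correlation (adjusted p = 0.141, 0.173 and 0.144). The oligodendrocyte list was not called (camera adjusted p = 0.309), with 5 of 10 up, 3 down and 2 not called, and MBP rose by 1.64 ± 0.21. The mesenchymal and pericyte list was not called (camera adjusted p = 0.762), with 5 of 14 up, 3 down and 6 not called; RGS5 rose by 2.24 ± 0.22, COL3A1 fell by 1.78 ± 0.19 and COL1A1 was not called (0.17 ± 0.16). Epithelial and endoderm markers (camera adjusted p = 0.53, directional fry 0.00489) had 1 of 7 up, 2 down and 4 not called, and SOX17 was at least 258-fold higher, from no vehicle count to 10.6 ± 1.47 CPM. EPCAM, which fell, lost its call without ITC replicate 1 (edgeR adjusted p = 0.0589). Muscle and neural crest markers (camera adjusted p = 0.111, directional fry 0.00601) had 2 of 10 down and 8 not called, with TFAP2B falling by 1.89 ± 0.38. The other that fell, DCT, lost its call without vehicle replicate 3 (edgeR adjusted p = 0.076) or ITC replicate 1 (0.129). Lists with fewer than 5 tested members had no list test; all 4 tested endothelial markers rose but stayed under 10 CPM, with TIE1 losing its call in several fits, KDR without ITC replicate 3 (edgeR adjusted p = 0.0612) and FLT1 with limma on log2(FPKM + 1) (adjusted p = 0.0544), the microglial marker ITGAM rose to 1.47 ± 0.262 CPM, and of 3 pluripotency markers DNMT3B fell by 1.60 ± 0.28 and DPPA4 by 0.60 ± 0.17, with LIN28A not called (-0.71 ± 0.95). Counts adjusted over the list alone were the same for every marker list.

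Over all lists, camera with a preset correlation of 0.01 called 24 of the 32 lists with at least 5 tested members, 18 up and 6 down. With an estimated correlation 6 remained. The estimate was below 0.01 in some lists, such as chemokines (-0.02), whose camera p still moved from 8.49e-14 to 0.0013. A call lost with an estimated correlation is therefore not by itself a sign of correlated members. Directional fry called 28 of the 32 and mixed fry 31. As 39.4% of all tested genes were called, a fry call does not set a list apart from other genes. The authors' deposited comparison called 6612 genes at an adjusted p under 0.05, 3491 higher and 3121 lower in ITC. Of these, 6178 were also called by edgeR, 3284 higher and 2894 lower in both, with 0 in opposite directions. The authors' deposited table alone called 434 genes, of which 359 were not tested by edgeR, and edgeR alone called 421.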

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

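All alternatives but library size only, which was chosen after seeing the data, were set before the data were examined; pseudocounts meant for a file without counts were not run because counts were present. In the 20 alternative settings 0 genes called in the main comparison were called in the opposite direction. Requiring at least 2-fold left 3588 genes, 1680 higher and 1908 lower, and an adjusted p under 0.01 left 2082 lower, both by construction; with library size only 4804 were lower, where the cause is the shift of all genes. Leaving out each library gave 5136 to 6955 genes (2470 to 3420 higher, 2480 to 3597 lower), with fewer samples. With an estimated inter-gene correlation 6 of the 24 list calls remained. The first principal component held 80.1% of the variance of all tested genes. The labels do not say that a replicate number marks a batch, so the main fit did not pair the numbers. Deviations of same-numbered libraries correlated at 0.27, 0.01 and 0.38. Vehicle replicate 2 correlated best with ITC replicate 1 (0.07). Replicates 1 and 3 correlated best with their own number, and crossed at -0.34 and -0.3. The second principal component was 8.4, -0.2 and -8 for vehicle replicates 1, 2 and 3, and 8.4, -3.1 and -5.5 for ITC. Pairing by number is therefore left open. With the replicate block 8416 genes were called, 4332 higher and 4084 lower, and 23 lists, the complement list not among them (adjusted p = 0.0936). Of the 193 named genes called, 23 lost the call in at least 1 alternative, and 15 uncalled named genes passed in at least 1, in the same direction, among them IL33, SERPING1, FKBP5, MDK, TYMS and SPARC; the cause was not tested.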

Other observations

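The gene families below were defined by symbol after the data were seen, so their tests were chosen after the results. Of 22 families, 20 had enough members to test, camera called 8, and 0 stayed called with an estimated correlation. Genes named here were picked after their values were seen. Of 13 tested TNF receptor superfamily genes, some of which are also in the receptor and apoptosis lists, 10 rose and 2 fell, with a median log2 change of 2.12 (adjusted p = 0.204 with an estimated correlation). TNFRSF9, a costimulatory receptor, rose by 8.66 ± 0.36, TNFRSF19 by 3.61 ± 0.17, to 863 ± 51.9 CPM (SD, n = 3), and the decoy receptor TNFRSF11B by 2.94 ± 0.33, while TNFRSF25 fell by 1.71 ± 0.34. Of 6 Toll-like receptors, 4 rose (adjusted p = 0.528 with an estimated correlation), TLR2 by 7.22 ± 0.44 from 0.160 ± 0.238 CPM. Of 27 replication-dependent histone genes, 10 rose and 1 fell (adjusted p = 0.508 with an estimated correlation), with HIST1H2BK rising by 1.17 ± 0.16. The libraries were poly-A selected, so these counts cover polyadenylated histone transcripts only and do not give total histone mRNA. Of 37 proteasome subunits, 9 rose and 1 fell, with a median of 0.23 (adjusted p = 0.652 with an estimated correlation). The largest rises were PSMB9 (5.05 ± 0.3), PSMB8 (4.37 ± 0.25) and PSMB10 (2.64 ± 0.23), which are also in the class I list. The other called rises were 0.43 to 0.9. The camera call was lost with upper quartile scaling (adjusted p = 0.0588) and with library size only (0.0958), where 4 rose and 3 fell and the median was 0.

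In other families more genes fell than rose. Of 78 cytosolic ribosomal protein genes, 39 fell and 1 rose, with a median of -0.56 (adjusted p = 0.652 with an estimated correlation), and the number that fell was 53 with upper quartile scaling and 64 with library size only; RPS23 fell by 0.84 ± 0.17 and RPS3A by 0.96 ± 0.22, and these genes have many pseudogene copies. Of 33 kinesins, 17 fell and 4 rose (adjusted p = 0.508 with an estimated correlation). The mitotic motor KIF15 fell by 5.58 ± 0.27 and KIF20A fell by 5.17 ± 0.33, while the transport motor KIF1C rose by 1.08 ± 0.18. KIF11 and KIF20A are also in the cell cycle list. Of 57 potassium channel genes, 23 fell and 8 rose (adjusted p = 0.508 with an estimated correlation), with KCNN3 falling by 3.28 ± 0.27 and KCNMA1 rising by 1.74 ± 0.15; its camera call was lost with upper quartile scaling (adjusted p = 0.0842) and library size only (0.138). Of 11 axonemal dynein heavy chains, 7 fell and 0 rose (adjusted p = 0.508 with an estimated correlation), DNAH6 by 2.34 ± 0.44, in the libraries where FOXJ1 also fell. DNAH5 and DNAH9, like FOXJ1, are also in the choroid plexus and ependymal list.

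The tests of explanations below and the splits for genes were chosen after the result was seen, except the test of other olfactory receptors and the splits for lists. The cell cycle list fell in ITC. Scaling is argued against as the whole cause, since a library factor moves all genes alike while the mean log2 CPM of the list relative to all tested genes of the same library differed by -3.42 between the groups (pooled SD 0.14, n = 3 per group). A loss of progenitor cells may contribute, as progenitor markers had a median of -1.31 (adjusted p = 0.173 with an estimated correlation), smaller than the fall of the list, and it cannot be told apart from lower cycling per cell in bulk RNA. An arrest with higher CDK inhibitor mRNA stays open as a hypothesis, with 3 of 7 inhibitors higher (CDKN2B by 4.25 ± 0.17, CDKN2A by 3.56 ± 0.24 and CDKN1A by 1.43 ± 0.17) and 2 lower.

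OR2I1P rose from no count. A general rise of olfactory receptors is argued against, since of 5 other tested receptor genes, pseudogenes included, edgeR called 0 higher and 1 lower, though 5 genes are few. Reads of GABBR1 as expressed in vehicle are argued against, as OR2I1P had 0 vehicle counts where GABBR1 had 6208 and GABBR1 was not called (-0.37 ± 0.25). Only 8.5% of GABBR1 exon bases lie in OR2I1P exons, so its counts cannot test a rise of reads from that part alone, which stays open. Reads of UBD, an inflammation-induced ubiquitin-like gene that was not analysed here, may be counted in OR2I1P, as 76.9% of UBD exon bases lie in OR2I1P exons on the opposite strand. Whether the counting used strand is not given in the sources used here, so this cannot be told apart from transcription of OR2I1P.

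More astrocyte identity genes fell than rose (adjusted p = 0.314 with an estimated correlation). Scaling is argued against as the whole cause, since the mean log2 CPM of the list relative to all tested genes of the same library differed by -0.76 between the groups (pooled SD 0.18, n = 3 per group). A lower share of astrocytes could raise markers of other types. The levels of 4 of 10 marker lists (neuron -0.71, progenitor -0.67, choroid plexus and ependymal -0.48, muscle and neural crest -0.38) were lower in ITC by more than 3 pooled SD. Those of 2 lists were higher (endothelial 0.43, microglial 0.13), both with 0 members at 10 CPM or more. Whether the astrocytes themselves express the markers that fell was not tested. These levels therefore cannot decide whether the share of astrocytes fell. In the 7 lists with a list test 33 of 75 members were lower and 13 higher, none of the 3 list calls remained with an estimated correlation (adjusted p = 0.141, 0.173 and 0.144), and a gain of the types that rose or of unlisted ones stays open. A response of the astrocytes to ITC is a hypothesis that these data do not separate from a change in cell composition.

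With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In every split but the real, each group mixes vehicle and ITC libraries. The treatment effect then adds to the spread within groups and partly remains between them. Counts of these other splits are therefore not levels without a treatment effect, and no conclusion is drawn from them. The real split called 6599 genes and the highest other 0, and 1 of the 10 splits, the real one, reached its count. For lists, the real split called 24 and the highest other 19, with 1 of the 10, the real one, reaching its count, and camera with a preset correlation called between 8 and 19 lists in the other splits.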
